A study of Bifidobacterium breve with 66 samples.

How the data were processed

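Total DNA of *B. breve* strains was labelled and hybridised against UCC2003 DNA on Agilent arrays overnight at 65 degrees, per the labels' protocols. Cells had been grown at 37 degrees to an optical density of 0.7, and the arrays were designed for the 1864 annotated genes of UCC2003, per the labels. Cy3 carried UCC2003 and Cy5 the test strain on every array, per the labels. Scans were converted with Agilent Feature Extraction 9.5, per the submitters' processing notes. The deposited scanner files hold each spot's intensity in both channels (mean, local background and processed signal), and the processed intensity is already background-subtracted and dye-normalised, per the file headers. The deposited scanner files also hold a log10 ratio of Cy5 over Cy3 per spot. The authors' value table holds the same log10 ratios rounded, and in 60 of the 61 arrays on the main format its column matched the scanner file. The column of DRBB28 did not match beyond its first rows. Of the strains with no scanner file, the columns of NRBB10 and NRBB11 also held log ratios only in their leading rows, and the values of NRBB20 stopped following earlier repeats of the same probe further down. The medians of the matching columns ran from -0.149 to 0.0938 log10 units, and their scale, centring and direction are those of the scanner files. For strains with no scanner file the same scale and direction were assumed and stay unknown. Further processing and clustering by the authors was not used here. All arrays but that of NRBB57, which was extracted with a different protocol, used one extraction protocol, per the file headers.

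The log2 ratio of processed Cy5 over processed Cy3 signal was computed from the deposited intensity values, and each array was centred on its median over non-control probes, without loess or quantile steps. Control spots and spots flagged as outliers were left out, between 0 and 48.2% of spots per array with a median of 0.468%, and saturated spots were kept. Repeat spots of a probe were averaged, and a gene took the median over its probes and needed at least 3. Of 1843 loci on the array, 24 had fewer probes and were left out. The 43803 non-control spots stood for 8262 probes, and 6 probe sequences were shared between loci. Median SD of repeat spots was 0.09 log2 units over arrays, and median SD between probes of a conserved gene was 0.13. A gene was called lower at a log2 ratio at or below -1 and higher at or above 1. Where every probe of a gene was not well above background in the Cy5 channel, the gene had only a bound on that array, taken per probe from the larger of its own signal and the lowest signal among well-above-background spots. Such arrays entered a fold change as "at least".

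Strains were grouped by the strain named in the labels, with 1 array each. Counts across strains used the main format. Arrays on the smaller format and strains known only from the value table were reported apart. From the value table, blocks of 1000 rows from the top were used as long as values stayed within 10 units and followed earlier repeats of the same probe with a correlation of at least 0.5. The plan before the data were examined counted strains that differed by less than array noise once. This was kept only for the rescanned array, because the labels name separate strains for the others, and counting near-identical strains once was added as an alternative. Correlations of each test array with the median profile of the others ran from -0.112 (NRBB39) to 0.852, and the lowest correlation of 2 arrays over all probes was -0.676. The labels state the dyes, so the direction was kept on every array.

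Variable regions were runs of at least 5 genes each lower in at least 10% of strains. Gene lists were written before the data were examined, by locus tag from background knowledge of UCC2003, and are not paired with names by the files. Lists that needed product descriptions, such as restriction-modification genes, were not analysed here because no annotation with UCC2003 locus tags was used. A list's mean share of strains was set against 10000 random lists matched on Cy3 signal in 10 classes. Jaccard distances and complete linkage followed the clustering method named in the labels. Genes were named by a rule fixed beforehand: the 15 genes lower in most strains, the 2 lower in most and the 1 lower in fewest strains of each list, the first, last and most often lower gene of the 10 longest regions, and the 5 genes with the highest median ratio. Intervals on shares are Wilson 95% intervals.

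Calls, regions and lists were tested on simulated data. On the self-hybridisation with 200 genes lowered, all 50 genes lowered by 1.5 log2 units and all 50 lowered by 2 were called. Of the 1619 unchanged genes among 1819, 0 were called. That array had 0 lower genes before any were lowered. Its median SD between probes of a conserved gene was 0.036 log2 units, against a median of 0.13 over arrays. The simulation therefore checks the steps and cannot give error rates for the noisier test arrays or for genes near the threshold. Alternatives covered thresholds, background correction, loess, probe filters, the value table, further arrays, noisy arrays, and leaving out slides or strains. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 (normexp with an offset of 50, loess with a span of 0.3).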

Results

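Genomic DNA of *Bifidobacterium breve* strains was hybridised to oligonucleotide arrays that carry the genes of strain UCC2003, a gut bifidobacterium used here as the reference. Each array compared 1 test strain, labelled with Cy5, with UCC2003, labelled with Cy3. A low Cy5 to Cy3 ratio could mark a UCC2003 gene that the test strain lacked or carried in a sequence too different to hybridise fully. The series held 66 arrays, of which 62 had scanner files. The main array format had 45220 spots, and 61 arrays used it, including 1 array on which UCC2003 was hybridised against itself. The arrays measured 1819 genes with at least 3 probes each. Each strain was represented by 1 array, so the number of arrays limits the precision and no p-value was computed across genes. NRBB29 and NRBB35 gave spot deviations with a Spearman correlation of 0.957 across spots, against 0.501 for the next highest of the 1830 pairs of arrays, and their file headers named the same slide and position. They were treated as 1 array scanned more than once, averaged and counted as 1 strain, which left 59 test strain profiles. Median Cy5 signal over genes lay between 367 and 1374 intensity units on the test arrays, and NRBB16 was the dimmest of them.

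The first question was how many UCC2003 genes gave a lower signal in each strain. The median test strain had 220 genes with lower signal (log2 ratio at or below -1), which was 12.1% of the genes measured. The middle range of strains, from the lower to the upper quartile, ran from 198.5 to 235 genes. NRBB07 had 314 lower genes, NRBB09 had 311, NRBB46 had 283, NRBB42 had 279 and NRBB44 had 273. At the other end NRBB39 had 0, NRBB38 had 2, NRBB16 had 30, NRBB06 had 85 and NRBB05 had 154. Resampling the probes of each gene 100 times moved these counts by an SD of at most 7.04 genes on any array, and the UCC2003 self-hybridisation had 0 lower genes. Both lower genes of NRBB38, named after their values were seen, were neighbours, Bbr_1072 at -3.94 and Bbr_1073 at -4.40, and the gene with the next lowest ratio on that array was Bbr_0516 at -0.34. In 5 arrays (NRBB05, NRBB06, NRBB16, NRBB17 and 017W4-21) the tRNA and 16S rRNA probes lay at a median log2 ratio of 1.28 to 2.61 above the array median. The other test arrays reached at most 0.32. Because every array was centred on its median, counts from the 5 arrays may not compare with those of other strains. The low counts of NRBB16, NRBB06 and NRBB05 therefore do not show a gene content close to that of UCC2003. On NRBB16 only 21.5% of Cy5 spots were well above background. Without the 5 arrays the count of lower genes per strain was 221.5. With loess normalisation the median fell to 127 genes per strain. At a threshold of -2 it was 150, so a call at -1 does not by itself show that a gene was absent.

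**Figure D1:**
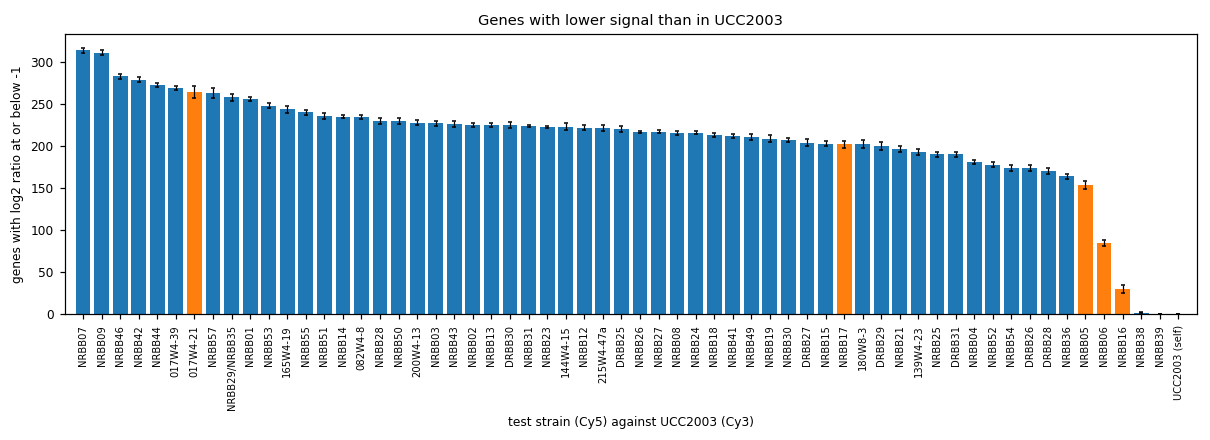
Genes with a log2 ratio at or below -1 (vertical axis, number of genes) for each test strain and for UCC2003 against itself, with bars for counts and whiskers for the SD over 100 resamplings of probes. Orange bars are the 5 arrays with raised tRNA and 16S ratios. Counts run from 314 in NRBB07 to 0 in NRBB39 and in the self-hybridisation.

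At the main setting 1171 genes (64.4%) were lower in no test strain and 648 were lower in at least 1, of which 118 were lower in exactly 1 strain. Leaving out 1 strain at a time gave up to 1217 genes lower in no strain, so many of those 118 came from 1 array. Lower signal in at least 50% of the strains was found for 219 genes. This count was 235 without the 5 arrays with raised tRNA and 16S ratios, 108 at a threshold of -2 and 70 with loess normalisation, and the count of genes lower in no strain was 858 with a threshold split per array, 993 with normexp and 1263 without the same 5 arrays.

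The genes lower in most strains lay in 3 stretches. In the stretch around Bbr_0311, that gene was lower in 55 of the 59 strains (93.2%, 95% Wilson interval 83.8 to 97.3, which treats related strains as independent). Its UCC2003 signal was at least 12.9-fold brighter in the median strain with a lower signal, and its median log2 ratio over all strains was -3.65. Its neighbours Bbr_0310 (55 strains, median -3.55) and Bbr_0306 (55 strains, median -2.89) were lower in as many strains. Bbr_0312, Bbr_0304, Bbr_0305, Bbr_0308 and Bbr_0307 were each lower in 54 strains, with median log2 ratios of -3.45, -3.42, -3.24, -3.04 and -2.99. In the stretch around Bbr_1119, Bbr_1118, Bbr_1119, Bbr_1120 and Bbr_1121 were each lower in 55 strains, with medians of -2.99, -3.34, -3.09 and -2.95. The third stretch was the exopolysaccharide cluster, whose genes Bbr_0440, Bbr_0436 and Bbr_0441 were each lower in 54 strains at medians of -3.23, -3.10 and -3.03. Cy5 signal was not well above background for Bbr_0440 in 23 of its lower strains, for Bbr_1118 and Bbr_0304 in 16 each and for Bbr_1119 in 14. The median log2 ratios took these signals at face value, so they can overstate the loss of signal. Only the fold changes used bounds. In the median strain with a lower signal UCC2003 was at least 7.53-fold brighter for Bbr_0440, 8.60-fold for Bbr_1118, 9.73-fold for Bbr_0304 and 11.3-fold for Bbr_1119. The other genes of these stretches had 1 to 12 such strains, with 12 for both Bbr_1121 and Bbr_0441 (each at least 7.71-fold). The bounds were 11.6-fold for Bbr_0310, 11.2-fold for Bbr_0312, 9.49-fold for Bbr_0436, 9.43-fold for Bbr_0305, 9.16-fold for Bbr_1120, 8.35-fold for Bbr_0308, 7.72-fold for Bbr_0307 and 7.16-fold for Bbr_0306. With loess normalisation Bbr_1118, Bbr_1119, Bbr_1120 and Bbr_1121 were lower in 29, 30, 29 and 31 strains, and Bbr_0305, Bbr_0306, Bbr_0307 and Bbr_0441 in 33, 30, 31 and 32. In the self-hybridisation Bbr_0311, Bbr_1119 and Bbr_0440 had log2 ratios of 0.08, 0.01 and 0.14.

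The second question was where the variable genes lay. A variable region was a run of at least 5 neighbouring genes that were each lower in at least 10% of the test strains. There were 26 such regions with 328 genes, which held 83.2% of the 394 genes lower in at least 10% of strains. The longest had 36 genes, from Bbr_0433 (53 strains) to Bbr_0472 (6 strains), and overlapped the exopolysaccharide cluster; its gene lower in most strains was Bbr_0440. Without the 5 arrays with raised tRNA and 16S ratios Bbr_0472 was lower in 2 strains, and at a threshold of -2 it was lower in 0 strains and Bbr_0433 in 27. A region of 35 genes ran from Bbr_1508 (29 strains) to Bbr_1548 (36 strains), with Bbr_1521 lower in 52 strains. Its Cy5 signal was not well above background in 12 of them, and UCC2003 was at least 7.69-fold brighter in the median strain with a lower signal. Bbr_1508 was lower in 14 strains at a threshold of -1.5 and in 4 at -2. A region of 23 genes ran from Bbr_1066 (6 strains) to Bbr_1088 (14 strains), with Bbr_1085 lower in 47 strains. With loess normalisation these 3 genes were lower in 2, 7 and 27 strains, and Bbr_1088 was lower in 8 at a threshold of -2. A region of 22 genes ran from Bbr_0197 (26 strains) to Bbr_0220 (28 strains), and it was lower as a whole in 19 strains and had no lower gene in 25. Bbr_0204 was its most often lower gene, in 33 strains, with UCC2003 at least 7.17-fold brighter in the median of them.

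The region of 20 genes from Bbr_0299 (42 strains) to Bbr_0321 (52 strains) had the highest mean share of the 10 longest regions, 86.4% of strains per gene. It had no lower gene in 3 strains, NRBB06, NRBB38 and NRBB39. NRBB06 is among the 5 arrays with raised tRNA and 16S ratios, and NRBB38 and NRBB39 had almost no lower genes anywhere. Whether these strains carry the region is therefore uncertain. At a threshold of -2 Bbr_0299 was lower in 17 strains and Bbr_0321 in 32, and with loess normalisation Bbr_0299 was lower in 27. A region of 18 genes from Bbr_1415 (8 strains) to Bbr_1432 (34 strains) had Bbr_1428 lower in 37 strains, and a region of 16 genes from Bbr_1788 (13 strains) to Bbr_1803 (11 strains) had Bbr_1792 lower in 38. Loess normalisation gave 4, 22 and 24 strains for Bbr_1415, Bbr_1432 and Bbr_1428, and 24 and 3 for Bbr_1792 and Bbr_1803. At a threshold of -2 Bbr_1415 was lower in 5 strains, Bbr_1788 in 3 and Bbr_1803 in 0, while Bbr_1803 was lower in 20 with uncorrected mean signals and 19 with normexp. A region of 14 genes from Bbr_0819 (29 strains) to Bbr_0836 (19 strains) had Bbr_0821 lower in 34. These counts were 12, 12 and 15 with loess normalisation, and at a threshold of -2 Bbr_0819 was lower in 15 strains and Bbr_0836 in 3. The region of 13 genes from Bbr_0018 (15 strains) to Bbr_0034 (10 strains) had no lower gene in 42 strains, and Bbr_0020 was lower in 17. Those 42 include NRBB06, NRBB16, NRBB38 and NRBB39, where the lack of a call does not show that the region was kept. Bbr_0034 was lower in 1 strain at a threshold of -1.5 or with a threshold split per array, and in 6 with loess. The region of 12 genes from Bbr_1400 (6 strains) to Bbr_1411 (33 strains) had Bbr_1409 lower in 34, and these were lower in 2, 17 and 20 strains with loess. When at least 80% of probes had to pass the threshold, Bbr_1788 was lower in 0 strains, Bbr_0836 in 4 and Bbr_0034 in 5. With near-identical strains counted once, Bbr_1788 was lower in 7 strains and Bbr_1803 in 6.

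**Figure D2:**
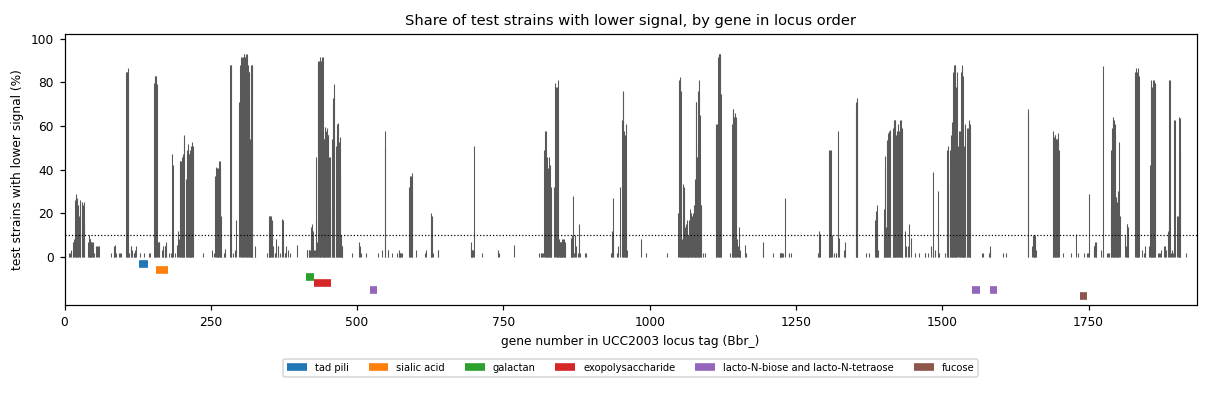
Percentage of the 59 test strains with lower signal (vertical axis) for each gene against its number in the UCC2003 locus tags (horizontal axis), with coloured bars under the axis for the gene lists and a dotted line at 10%. Tall blocks are the variable regions, and one of them holds most of the exopolysaccharide list, while the tad pili, lacto-N-biose and fucose lists lie where few or no strains were lower.

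**Figure D3:**
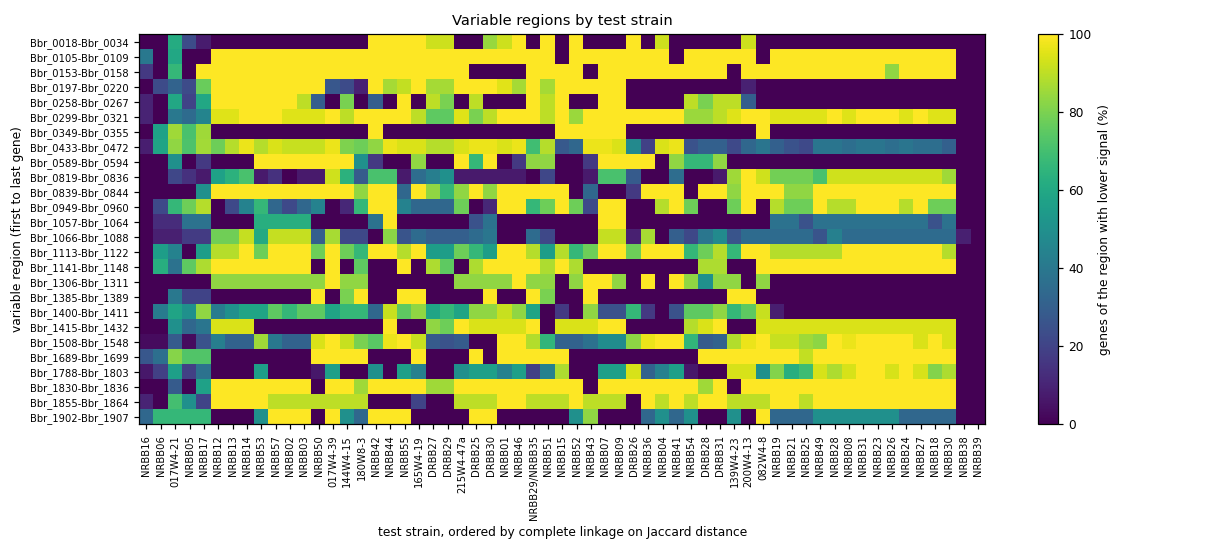
Percentage of the genes of each of the 26 variable regions that had lower signal (colour) in each of the 59 test strains, ordered by complete linkage. NRBB39 is dark in all regions and NRBB38 in all but the region from Bbr_1066, and regions such as Bbr_0105-Bbr_0109 are lower as a whole or have no lower gene in most strains.

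Gene lists fixed beforehand from locus tags differed widely in their shares of strains. The exopolysaccharide list (surface polysaccharide synthesis) had 21 measured members, all of them lower in at least 1 strain and 19 of them in at least 50% of strains. Its mean share was 68.0% of strains, above all of the 10000 random lists matched on Cy3 signal, whose median was 36.8%, and at the 99.0th percentile of all rotations of the list along the gene order. Cy3 signal was the median over all arrays, nearly all with test DNA in the other channel. The matching classes may therefore depend on gene loss themselves, and 36.8% is well above the 12.1% of genes lower in the median strain. Rotations do not use these classes. The list member lower in fewest strains was Bbr_0431, in 4 strains and in 2 without the 5 arrays with raised tRNA and 16S ratios. With normexp Bbr_0431 was lower in 11 strains, and with uncorrected mean signals in 7. With loess normalisation it was lower in 0 strains and the mean share was 41.2%.

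The other lists had low mean shares of strains with lower signal. None of the 17 measured genes in the list for lacto-N-biose and lacto-N-tetraose use, which serves the breakdown of milk sugars, was lower in any strain at the main setting. Bbr_0526, Bbr_0527 and Bbr_0528 were lower in 0 of the 58, 59 and 58 strains that measured them, with medians of 0.02, -0.09 and -0.07. With a threshold split per array Bbr_0526 was lower in 3 strains and Bbr_0527 in 2, and the mean share of the list was 0.803% of strains, against 0.700% with normexp, 0.504% with loess and 0.301% with uncorrected mean signals. Of the 7 genes for tad pili, thin surface fibres for attachment, only Bbr_0136 was lower, in 1 strain where it lay at the threshold, and in no strain when the probes were averaged by the mean. It was lower in 3 strains with a threshold split per array and in 2 with normexp, and the mean share of the list was 4.92% of strains with the split threshold, 1.21% with normexp and 0.242% at the main setting. Bbr_0132 and Bbr_0137 were lower in no strain, and with a threshold split per array in 1 and 3. Of the 4 fucose genes, Bbr_1742 was lower in 1 strain at -1.04, while Bbr_1740 and Bbr_1741 were lower in none. With a threshold split per array Bbr_1742 was lower in 4 strains and Bbr_1741 in 3, and at a threshold of -1.5 Bbr_1742 was lower in 0. The mean share of the fucose list was 0.424% of strains, and 3.83% with the split threshold. Of the 12 sialic acid genes, Bbr_0160 and Bbr_0162 were lower in 4 strains each, with medians over those strains of -1.63 and -1.85, and Bbr_0163 in none. With normexp Bbr_0160 was lower in 8 strains and Bbr_0162 in 10, at a threshold of -2 in 0 and 1, and with a threshold split per array Bbr_0163 was lower in 3. The mean share of the sialic acid list was 3.54% of strains, 6.80% with normexp, 1.13% at a threshold of -1.5 and 0.141% at -2. Of the 6 galactan genes, Bbr_0422 was lower in 8 strains with a median log2 ratio of -2.86 over those strains, Bbr_0418 in 2 and Bbr_0419 in none. With a threshold split per array Bbr_0422 was lower in 13 strains, at a threshold of -2 Bbr_0418 was lower in 0, and with normexp Bbr_0419 was lower in 2. Mean shares of these lists lay at the 0th (lacto-N-biose), 8.09th (tad pili), 23.8th (fucose), 23.5th (sialic acid) and 55.0th (galactan) percentile of random lists. Among rotations of each list along the gene order, which keep neighbours together, they lay, in the same order, at percentiles of 0, 30.3, 42.6, 55.9 and 66.7. Percentiles counted lists with a share strictly below the observed one. Both percentiles of lacto-N-biose were therefore fixed at 0 by its share of 0 and do not show how unusual it was. The median share of its random lists was 6.98%.

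Higher signal in a test strain was concentrated in 5 arrays. The median strain had 3 genes with a log2 ratio at or above 1, while 454 genes were higher in at least 1 strain. The counts were 242 in 017W4-21, 210 in NRBB17, 196 in NRBB16, 177 in NRBB05 and 130 in NRBB06, and these 5 arrays with raised tRNA and 16S ratios held 79.5% of all such calls. Their counts of higher genes also depend on centring each array on its median. The 5 genes with the highest median log2 ratio over strains were Bbr_0928 (0.70, higher in 11 strains), Bbr_0933 (0.58, 6 strains), Bbr_0925 (0.56, 17 strains), Bbr_0930 (0.44, 5 strains) and Bbr_0807 (0.43, 6 strains), and none was lower in any strain at the main setting. With uncorrected mean signals Bbr_0928 was lower in 6 strains and Bbr_0933 in 1, and with normexp in 9 and 4, with Bbr_0925 lower in 1. Their log2 ratios in the self-hybridisation lay between -0.09 and 0.06. Depending on the setting the median count of higher genes per strain was between 0 and 12.

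The last question was how alike the strains were. The median Jaccard distance between the sets of lower genes, taken over genes measured in both strains, was 0.548 over 1711 pairs, and complete linkage gave 17 clusters at a distance of 0.5. This distance says little where sets are nearly empty. NRBB38 and NRBB39, with 2 and 0 lower genes, lay at a distance of 1.0 from each other. NRBB16, with 30 lower genes, lay at 0.92 or more from every other strain. Each of them therefore formed a cluster of its own. The closest pairs were NRBB23 and NRBB26 (217 shared lower genes and 0 lower in 1 of them alone), NRBB23 and NRBB31 (223 shared, 1 in one alone), NRBB26 and NRBB31 (217 shared, 1 in one alone), NRBB23 and NRBB27 (217 shared, 2 in one alone), and NRBB24 and NRBB27 (212 shared, 2 in one alone). Repeated scans of the NRBB29 and NRBB35 array differed in the call of 9 genes, so these pairs differed by less than the scans of one array. In all, 16 strains lay in 5 sets whose members were linked by differences of at most 9 genes, the largest holding NRBB08, NRBB18, NRBB23, NRBB24, NRBB26, NRBB27, NRBB30 and NRBB31. The sets include NRBB38 with NRBB39, which were linked because both had almost no lower genes. Spots flagged as outliers left 1670 genes measured in NRBB26. With loess normalisation the median distance was 0.789 and the number of clusters 37. Of the 59 strains, 56 shared a slide with another test strain, and 8 strains had their nearest neighbour on their own slide, against a median of 2 when slides were shuffled (1-sided permutation test, 100000 resamples, p = 0.0110). Of the closest pairs named above, only NRBB24 and NRBB27 shared a slide. Strains of one name series, such as DRBB, were placed together on slides. The shuffle therefore cannot tell a slide effect from related strains sharing a slide, and it treats near-identical strains as independent.

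**Figure D4:**
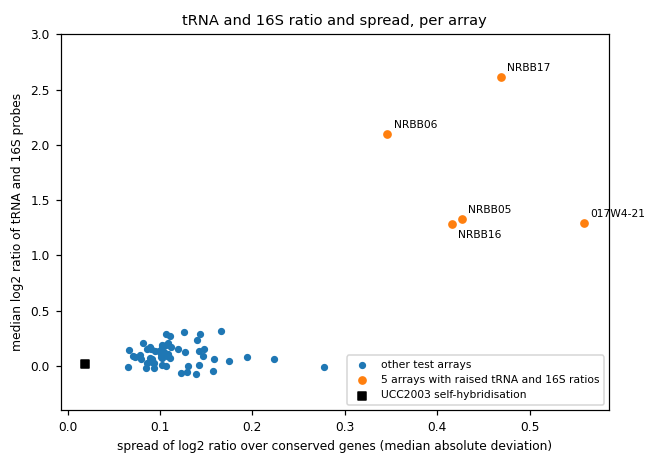
Median log2 ratio of tRNA and 16S rRNA probes (vertical axis) against the spread of log2 ratios over conserved genes (horizontal axis, median absolute deviation) for each test array and the UCC2003 self-hybridisation. The 5 arrays named in the plot lie at 1.28 to 2.61 and a spread of 0.346 or more, apart from all other arrays.

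The strains outside the main set gave shares of lower genes between 9.90% and 13.0% of the genes measured. The counts of NRBB10, NRBB11 and NRBB20 use only the leading rows of their columns in the value table. CNCM I-4321, on a smaller array format of 10807 spots, had 131 lower genes among the 1009 with at least 3 probes. Strains known from the value table had 180 lower genes of 1819 in NRBB48, 198 of 1792 in NRBB20, 214 of 1734 in NRBB10 and 63 of 546 in NRBB11. NRBB10 also had 219 higher genes.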

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

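The arrays also carried targets outside the UCC2003 chromosome, which no comparison above used. The criteria were chosen after these values were seen: a Cy5 signal of at least 10% of the median gene, at least 2 times the brightest spike-in control target of the same array, and at least 80% of spots well above background. The UCC2003 self-hybridisation met them for no target. The target TetW, named for a tetracycline resistance gene, had a Cy5 signal of 855% of the median gene in NRBB17, 342% in 139W4-23, 169% and 171% in the repeated scans labelled NRBB29 and NRBB35, 130% in DRBB25 and 70.5% in NRBB43. On NRBB17 the tRNA and 16S probes lay at 2.61 log2 units above the array median. Its percentage of the median gene may therefore not compare with those of the other strains. The targets named pCIBb1, a bifidobacterial plasmid, reached 238% in NRBB04, where all 6 of its targets were above the spike-in controls. The target iss1 reached 49.2% in NRBB53 and 28.0% in DRBB30. In UCC2003 against itself TetW, pCIBb1 and iss1 each lay at 0.5% of the median gene. Each value comes from 1 array.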

How the results depend on the processing

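Leaving out the 5 arrays with raised tRNA and 16S ratios, leaving out NRBB38 and NRBB39, counting near-identical strains once, and leaving out single strains were chosen after seeing the data. No paired analysis was possible because each strain had 1 array. Centring on ribosomal protein genes was not run, because those genes were not named in the sources used, and no array had an unsettled direction to turn. Apart from the cases below, the main counts of genes, regions and clusters stayed within 1.5 times, list shares within the 95% Wilson interval for 59 strains and distances within their spread, under the alternatives run. That interval is wide for small shares, and with a threshold split per array the tad pili share rose from 0.242% to 4.92% and the fucose share from 0.424% to 3.83%, while the sialic acid share was 6.80% with normexp, 1.27% when 80% of probes had to pass and 1.13% at -1.5, against 3.54%. With loess, the median strain had 127 lower and 12 higher genes, 70 genes were lower in at least 50% of strains, the median distance was 0.789, there were 37 clusters and the exopolysaccharide share was 41.2%; the cause was not tested. At a threshold of -2, 108 genes were lower in at least 50% of strains and the sialic acid share was 0.141%, as a stricter threshold makes fewer calls. The median count of higher genes was 0 at thresholds of 1.5 and 2, with normexp, with uncorrected mean signals, and when at least 80% of probes had to pass, and 7 with the mean over probes. Normexp gave 2 lower genes in the self-hybridisation. A distance of 1 minus Pearson correlation had a median of 0.421, on another scale. Without each slide in turn, the median strain had 217 to 222 lower genes, 1171 to 1223 genes were lower in none and 213 to 234 in at least 50% of strains. Among results outside the main ones, such as the counts for named genes, such runs moved 6 and left 1294 within the limits. Counts of strains for the 64 named genes moved by over 1.5 times for 33 genes with loess, 17 at a threshold of -2, 13 with normexp, 13 with a threshold split per array, 9 at -1.5, 9 when 80% of probes had to pass, 6 with uncorrected means, 4 without noisy arrays, 4 without the 5 arrays, 3 with near-identical strains counted once and 2 with the mean over probes. Signal over background limited NRBB16 most, with 21.5% of its Cy5 spots well above background.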

Other observations

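The tests of the 5 arrays with raised tRNA and 16S ratios and of NRBB38 and NRBB39 were chosen after the result was seen; so was that of slide for the wave along the gene order, whose other tests were set down before it was computed for arrays other than NRBB39. Genes lower in at least 50% of strains had probes with a mean GC content of 49.2%, against 51.7% for genes lower in no strain. None of the 1818 rotations of these genes along the gene order gave a GC content as low.

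NRBB05, NRBB06, NRBB16, NRBB17 and 017W4-21 differed from the other arrays in ratio over the whole genome, with a spread over conserved genes of 0.346 to 0.559 against a median of 0.107 elsewhere, and deviations of probes within genes correlated at 0.420 to 0.748 between these arrays. A GC trend left 0.876 or more of the spread, and the other arrays on the same slides reached a spread of at most 0.148. These values argue against GC and slide as the whole cause. With both scans of the NRBB29 and NRBB35 array counted, 49 other test arrays had Cy5 signal no brighter than any of these but NRBB16. They reached a spread of at most 0.224. That Cy5 signal was already dye-normalised, so this comparison cannot decide whether low signal was a cause. For NRBB16, low signal stays open as well, since 0 other test arrays had as few Cy5 spots well above background. DNA more diverged from UCC2003 over the whole genome also stays open, since the raised tRNA and 16S ratios, the lowest being 1.28, are what these arrays were picked by and so cannot test it. A mixed culture or a strain of another species was not tested.

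NRBB38 and NRBB39 had few or no lower genes. NRBB38 had 1 gene, Bbr_1072, with every probe at or below -2, which argues against an array that cannot register lost genes and against unmodified UCC2003 DNA in both channels. For NRBB39 there were 0 such genes, so a strain with the gene content of UCC2003, UCC2003 DNA in both channels and an array that cannot register lost genes cannot be told apart. Its log2 ratios did follow a wave along the gene order of 0.33 log2 units, against 0.02 in the self-hybridisation, so its 2 channels differed in this, but other strains had such waves too and all 3 stay open. A close relative or derivative of UCC2003 in NRBB38 is a hypothesis that was not tested.

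Log2 ratios of the 1171 genes lower in no strain followed a wave along the gene order, with a median height from trough to peak of 0.16 log2 units and up to 0.70 in NRBB50, against 0.02 in the self-hybridisation. The wave's peak or trough lay within 10% of the gene order of the first gene in 79.3% of 58 arrays (23 with the peak there and 23 with the trough), where chance gives 40% if arrays are independent. They were not: 75.1% of the variance of the wave at the first gene lay between slides, against a median of 32.8% in 10000 permutations of slides, and of the 20 slide means 9 had the peak and 7 the trough within the same distance. Slides were not uniform, however. Of the 17 slides with 2 or more arrays, 8 had the same sign of the wave at the first gene on all arrays, and the rest held both signs. Correction for GC left 0.994 of the median height, which argues against GC as the cause. Gene dose that changes with replication, if the gene numbering starts at the origin as in many bacterial genomes, and a batch of DNA or labelling that followed the slides both stay open as candidate explanations.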
